A study of Mus musculus with 2 samples.

How the data were processed

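Cells were sorted from tumour-draining lymph nodes of BP and BPT mice, stained with 4 hashtag antibodies, pooled and loaded on a droplet-based 3' single-cell platform, per the labels' protocols. The cDNA was amplified for 11 cycles and split by size into an mRNA-derived and a hashtag-derived library, per the labels' protocols. The submitters' processing notes name Cell Ranger and the mouse genome build GRCm39 (mm39). The version of Cell Ranger, the gene annotation and the settings used to call cells are not given in the sources used here.

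The 3 files used hold lists and no measurements: the authors' filtered cell barcodes, 1 per line; the features, each with an identifier, a symbol and a type; and the hashtag reference, with the sequence and its place in the read per the file headers. The table of counts was not used here, so the tests, clustering, hashtag calls and gene list comparisons planned for it were not run. Samples were grouped by library from their titles, and hashtags were tied to populations through the labels' protocols.

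Barcodes were counted as full lines and again with the suffix removed. Hashtag sequences were compared position by position from their first base, and by edit distance. Features were counted by identifier and by symbol. Identifiers without version numbers were matched to GENCODE M21 (GRCm38 primary assembly, 55536 genes). Of the 22545 listed mouse genes, 22455 (99.6%) were found there and 90 were not. M21 was used for gene types, gene symbols and the number of genes of each type. It was not used for coordinates, because its build differs from that of the files. Long noncoding genes were taken as its lincRNA, antisense, processed transcript, sense, bidirectional promoter, overlapping, macro and TEC (awaiting experimental evidence) types. T cell receptor and immunoglobulin segments were taken as all its types with the TR or IG prefix, including pseudogenes of those types. The comparison by position and the count of barcode pairs were tested on simulated sequences with known differences. The edit distance was checked there only against an upper bound. Python 3.11.15 and matplotlib 3.10.9 were used.

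The gene lists, the marker sets and the rule for named genes were fixed before the data were examined. Without counts, the rule names Tslp, Crlf2, Il7r and the list members as present or absent only. Braf, Tyr and the sort markers were named because the labels name them or their products, and the noncoding genes in the closing section were chosen after the feature list was seen. The lists are exact counts of entries, so they carry no replicate error. The depth of sequencing per cell is unknown, and no interval or detection limit was computed.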

Results

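The series set out to profile dendritic cells that had migrated to the tumour-draining lymph node, together with CD4+ T cells from the same nodes, in mice with primary melanoma that either carried or lacked Tslp. Tslp encodes thymic stromal lymphopoietin, an epithelial cytokine. In BP mice, melanocytes carry an activated Braf allele that topical 4-hydroxytamoxifen induces. BPT mice carry the same tumour model and are also deficient in Tslp. Nodes were taken at day 42. The sorts held migratory dendritic cells (B220-negative, CD11c-positive to intermediate, high in MHC class II) and CD4+ cells (negative for B220, CD11c, MHC class II and CD8a).

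The table of counts per cell was not analysed here, and with it gene levels, hashtag counts, cell type shares and the differences between BPT and BP cells. The data described are the list of cell barcodes, the list of features that goes with those barcodes, and the definitions of the hashtags. None of these is a measurement of expression. No gene, gene group or cell type can be called higher or lower in either genotype from them, and the depth per cell is unknown.

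The 4 sorted populations were each stained with an antibody carrying its own DNA hashtag and combined in equal parts of 7500 cells, 30000 cells in all. The pool gave 2 libraries from the same droplets, 1 of cDNA from mRNA and 1 of cDNA from the hashtags. Each combination of genotype and sort had 1 hashtag. The design therefore holds 1 sample for each side of the comparison of BPT with BP, in migratory dendritic cells and in CD4+ cells alike. A hashtag separates the populations but not the mice within one, and the labels used here do not give the number of mice. With 1 sample per group neither comparison can be tested against variation between animals.

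The filtered list held 15757 cell barcodes of 16 bases, all different from one another. This was 98.5% of the 16000 cells that the capture aimed for, and 52.5% of the 30000 cells pooled. A barcode in this list stands for a droplet called as holding cells, and droplets with more than 1 cell are counted among them. How the barcodes divide among the populations was not analysed here.

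The hashtag sequences were 15 bases long and were read from the start of the second read. BP CD4+ cells carried ACCCACCAGTAAGAC and BP migratory dendritic cells carried GGTCGAGAGCATTCA. BPT CD4+ cells carried CTTGCCGCATGTCAT and BPT migratory dendritic cells carried AAAGCATTCTTCACG. Any pair of these differed at 11 to 13 of the 15 positions. For the comparisons between genotypes, the hashtags of BP and BPT CD4+ cells differed at 12 positions and those of BP and BPT migratory dendritic cells at 13.

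The feature list held 22552 entries, of which 22545 were mouse genes, 3 were added sequences and 4 were the hashtags. Tslp (ENSMUSG00000024379), the gene that BPT mice lack, was listed. The genes for both chains of its receptor were listed as well, Crlf2 (ENSMUSG00000033467) for the TSLP-specific chain and Il7r (ENSMUSG00000003882) for the chain shared with the interleukin-7 receptor. Braf, activated in the tumour model, had 1 entry, as did Tyr, whose promoter drives the inducible recombinase. Genes behind the sort markers were present too, among them Cd4, Cd8a, Itgax (CD11c), Ptprc (whose product carries the B220 epitope) and H2-Ab1 (an MHC class II chain). No coordinates are given for these genes, since the annotation at hand is on GRCm38 and the submitters' processing notes name GRCm39.

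The gene groups chosen for this tissue before the data were examined were covered in full. They comprised 13 gene lists with 116 distinct genes and 19 sets of cell type markers with 99, together 194 distinct genes, and each of the 194 was in the feature list. The 194 genes were matched by symbol. The feature list held 89.84% of all M21 protein-coding genes by symbol and 98.18% by identifier. Most protein-coding genes were thus listed by either route. Whether the full coverage differs from that share was not tested, and it is not read as a trait of these groups or this tissue. Among the lists, the 11 genes of the TSLP receptor and STAT5 target list included Cish and Socs2, negative regulators of cytokine signalling. The 10 TSLP-associated dendritic cell genes included the chemokines Ccl17 and Ccl22, which attract cells bearing Ccr4, and Tnfsf4, the OX40 ligand. The 12 maturation genes included the chemokine receptor Ccr7 and the actin-bundling protein Fscn1, and the 12 antigen presentation genes included Ciita, the master regulator of MHC class II. The interferon list held 14 genes, such as Isg15 and Irf7.

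The helper T cell programmes were covered by lists of 6 genes for Th1 (Tbx21 and Ifng among them), 8 for Th2 (Gata3, Il4 and Il13), 6 for Th17 (Il17a and Il17f), 10 for regulatory T cells (Foxp3 and Il2ra) and 8 for follicular helper cells (Bcl6 and Cxcr5). The lists for naive and memory cells and for dissociation stress held 8 genes each, and that for proliferation held 6. The marker sets for dendritic cell types held 7 genes each for cDC1 (Xcr1 and Clec9a), cDC2 (Cd209a and Mgl2) and migratory mature cells, 5 for Langerhans cells (Cd207 and Epcam) and 6 for plasmacytoid cells (Siglech). The T cell sets held 5 genes for CD4 T cells, 4 for regulatory, 5 for naive, 5 for follicular helper and 3 for CD8 T cells. Cells that the sorts should exclude or could carry over were represented by 5 B cell genes, 4 plasma cell genes, 7 NK or innate lymphoid genes, 8 macrophage or monocyte genes, 4 neutrophil genes, 6 stromal genes, 3 keratinocyte genes, 6 melanocyte genes and 3 erythroid genes. These counts describe which genes were listed, not whether they were expressed.

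Compared by identifier with GENCODE M21, a mouse annotation, the feature list covered protein-coding genes and antigen receptor segments nearly completely and noncoding genes hardly at all. It held 21627 of 22028 protein-coding genes (98.2%), 270 of 270 T cell receptor segments and 427 of 432 immunoglobulin segments (98.8%). It held 33 of 13374 long noncoding genes (0.25%), 16 of 13235 pseudogenes outside the antigen receptor and polymorphic classes (0.12%), and 0 of 6115 small and other noncoding genes. These types are those of M21, and the types given by the annotation behind the feature list are not known. The 82 polymorphic pseudogenes of M21 were all listed by identifier, but only 18 of them (22.0%) by symbol. Of the mitochondrial genome, 13 genes named with the mt prefix were listed, and neither the 2 ribosomal RNA genes nor the 22 transfer RNA genes were. A mitochondrial share computed on this list would rest on those 13 genes.

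**Figure D1:**
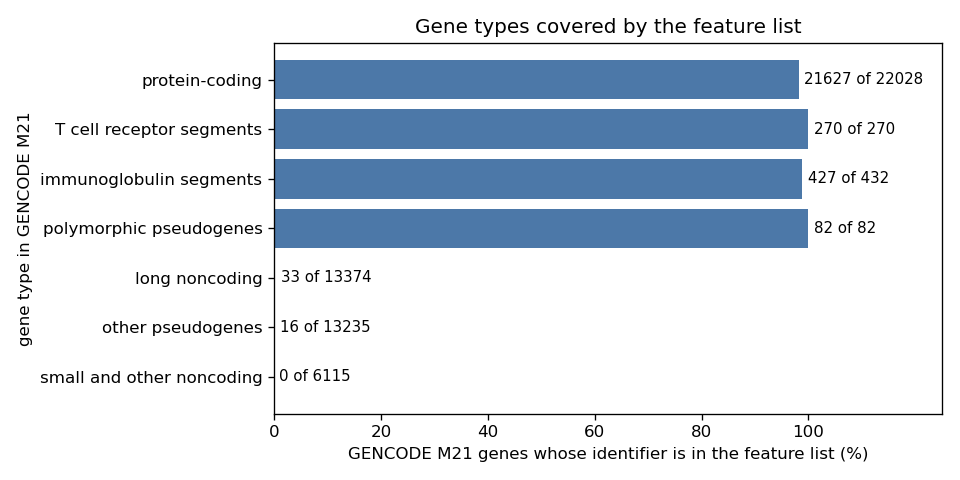
Share of the genes of GENCODE M21 whose identifier is in the feature list, in percent (horizontal axis), for 7 gene types (vertical axis); the text at each bar gives the number listed and the number in M21. Protein-coding genes (98.2%) and antigen receptor segments (98.8% or more) are nearly complete, whereas long noncoding genes are at 0.25%; these are counts from lists and have no error bars.

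The added sequences were named BFP, tdRFP and SV40PolyA, which are the names of a blue fluorescent protein, a tandem red fluorescent protein and a viral polyadenylation signal. The labels used here describe no fluorescent reporter in BP or BPT mice, and the levels of these sequences were not analysed here. No entry was named for the Cre recombinase carried by both genotypes.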

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

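Of the alternatives chosen before the data were examined, counting by symbol gave 22524 genes against 22545 by identifier. The other checks on counts could not move their values: the barcodes shared 1 suffix, so removing it left 15757, and all 194 genes of the fixed lists already matched exactly, so ignoring case could add none. These say nothing about stability. The smallest distance between hashtags was 8 by edit distance, for BP migratory dendritic cells and BPT CD4+ cells, which differ at 12 positions; by position it was 11, for BP CD4+ cells and BP migratory dendritic cells, whose edit distance is also 11. Matching to M21 by symbol, an alternative added after seeing the data, gave 89.8% of protein-coding genes against 98.2%, and 0.25% of long noncoding genes by either route. Polymorphic pseudogenes fell by symbol to 21.95% (18 of 82, against 82 by identifier). The rest were thus listed under symbols other than those that M21 gives. Why the symbols differ was not tested. T cell receptor segments (95.6%), immunoglobulin segments (98.1%) and other pseudogenes (0.14%) stayed within 1.5 times by symbol. The alternatives planned for hashtag calls, cell filters, scaling, thinning, clustering and gene lists were not run, because they need the table of counts. No paired analysis was possible because each population has 1 hashtag and no count was tested.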

Other observations

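The test in this part was chosen after the feature list was seen. Several long noncoding genes that are abundant in many single-cell libraries were not found by symbol: Malat1, Neat1 and Xist had 0 entries each. Their identifiers were not looked up. A change of identifiers between annotation releases is argued against, since only 90 listed identifiers were unknown to M21, too few to stand for the 13341 long noncoding genes of M21 that were not listed. What the list held followed gene type, with 98.18% of M21 protein-coding genes against 0.25% of long noncoding genes. Small and other noncoding genes had 0 of 6115 listed. Whether the annotation or a later step set this limit was not tested, so the step at which these genes were left out remains open. No biological explanation was tested. Unless Malat1 is listed under another symbol, counts made on this list could not show this nuclear noncoding RNA, often used to judge cell integrity.

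Of the listed genes, 40 identifiers shared 19 symbols. Among these were Ddit3, a transcription factor of the stress response, Aldoa, a glycolytic enzyme, and Nnt, a mitochondrial transhydrogenase, each with 2 identifiers, named after the list was seen. Tables joined by symbol would merge or drop such entries. None of the 194 genes of the fixed lists was among them.

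No pair of the 15757 barcodes differed at a single position, the count of such pairs being 0. The list was already filtered by the authors, so no conclusion on barcode errors is drawn from this count.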
